A study of Drosophila melanogaster with 2 samples.

How the data were processed

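The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of CG15696, a homeodomain gene of Drosophila melanogaster, in whole embryos aged 2 to 8 h of mixed sex. The flies carry a transgene that adds green fluorescent protein (GFP) to the C-terminus of CG15696, and the chromatin was precipitated with an antibody against GFP, per the labels. The labels put both samples in 1 group, as biological replicates numbered 1 and 3. There is no comparison between groups. The age was taken from the source name of the samples, since their age field holds a number of hours that no embryo could have. Chromatin was sheared by sonication, with a stated size range of 200 to 800 bp.

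The deposited files are peak lists on the dm6 assembly, per the labels. The authors called peaks separately on each replicate and on both replicates together, each time against the same 1 control alignment, per the notes deposited with the files. From these lists they derived a list thresholded by the irreproducible discovery rate (IDR), a measure of whether peaks keep their rank between replicates. The peak caller, its version, the IDR threshold and the read depth are not given in the sources used here, so no interval for sequencing depth could be given. Each peak carries the authors' signal value, whose scale is not stated, and it was used to rank and describe peaks within a list and, as a ratio between the replicate lists, to compare sites matched in both. The authors' −log10 q value per peak reaches a ceiling near 4 and was not used for ranking. It falls to 0.114 in the pooled list and to 0.0196 in that of replicate 3, so the full lists include weakly supported peaks. Each replicate list and the pooled list held 30000 peaks. The 5354 IDR sites were the 5354 pooled peaks of highest signal, so the IDR list and the top of the pooled list are the same set and an alternative built on the pooled list moves nothing.

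Sequence came from the RefSeq copy of the Release 6 genome and genes from Ensembl release 115. All peaks lay on the arms 2L, 2R, 3L, 3R, 4 and X, and none extended past the end of its arm. There were 13945 protein-coding genes on these arms. Each site was placed by its summit. A summit within 500 bp of the transcription start site (TSS) of a protein-coding transcript was called a promoter site, and other summits were assigned in order of priority to 5' UTR, coding exon, 3' UTR, intron, non-coding gene or intergenic sequence. The promoter share was compared with 10000 sets of random positions on the same arms (two-sided permutation test). Strong and weak sites were compared by Fisher's exact test (two-sided) between the 1338 sites of highest and the 1338 of lowest signal. The density on X was compared with the autosomal arms by an exact binomial test (two-sided).

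Replicate overlap was the share of IDR sites with a summit within 100 bp among the 5354 strongest peaks of replicate 1 and of replicate 3. Peaks just below the IDR list were compared with 100 circular shifts of the replicate summits along each arm. Signal was compared across sites by Spearman's and Pearson's correlation. Sites are not independent replicates, so these have no p-value, and the standard error came from 200 bootstrap draws over sites. Shares carry 95% Wilson intervals that cover counting error only.

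For 19 gene lists fixed before the data were examined, a gene counted as having a site when an IDR summit lay in its body or within 2 kb of it. The number of such genes was compared with 100000 random gene sets of the same size drawn within deciles of gene territory length (two-sided permutation test, Benjamini-Hochberg over the 19 lists). The smallest p this test can give is 2e-05. One listed symbol, tal, had no protein-coding match, and 4 others were matched through older or alternative symbols. For 20 preset motifs, and for all 2080 6-mers merged with their reverse complements, the share of sites with a match within 50 bp of the summit was compared with flanks of the same width centred 350 bp away in the same sites (exact sign test, two-sided, Benjamini-Hochberg within each family). The alternative control was random positions on the same arm with GC content within 2% of the window. Ratios used the mean of both flanks, or of both draws of random positions. The sign test used a single flank or draw per site, picked at random, so a ratio and its p do not rest on the same counts.

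The genes named in the text are those whose protein-coding TSS is nearest to each of the 20 strongest sites, up to 4 members of each list with the strongest site in their territory, and CG15696, except for 1 item that is not reported here. The 6-mers named are the 5 with the highest ratio of summit to flank among those past an adjusted p of 0.05 and in at least 5% of sites. Other genes or sequences named were chosen after their values were seen. The alternatives varied the replicates used, the threshold, the overlap rule, the promoter window, the set of TSSs, the strata, the assignment of sites to genes, the matching, the motif window and the motif control. The comparison of site classes with GC-matched positions, the assignment by a gene's own TSS, the split of the Notch and EGFR list, the position profiles and the comparison of sites by relative signal in the 2 replicates were added after seeing the data.

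The gene list test and the motif tests were tested on simulated data. With sites simulated over the 13945 genes, a planted 2-fold excess in the 85 ribosomal protein genes was found in 20 of 20 runs. In the 20 NKL homeobox genes it was found in 17 of 20, in the 15 Notch and EGFR targets in 3 of 20 and in the 8 Hox genes in 0 of 20. The planted share of genes with a site was capped, so genes with long territories received less than a 2-fold excess. An excess in a short list can therefore be missed. In the data, 60.2% of Hox genes were expected to have a site, so a 2-fold excess was not possible there. Lists simulated with no effect were called in 1 of 280 tests. Each gene was simulated independently, so false calls from adjacent genes that share a site were not covered. In 5000 simulated sequences both planted motifs were found and 0 of the 18 other preset motifs were called. Summits and flanks were simulated with the same base composition. False calls from a difference in GC content, which the data show, were therefore not covered. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.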

Results

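Binding of GFP-tagged CG15696 was mapped by ChIP-seq in whole Drosophila melanogaster embryos aged 2 to 8 h, in 2 biological replicates of 1 group. CG15696 is a homeobox gene of the NKL class. The IDR list, called the reproducible set here, held 5354 sites. These merged to 5176 regions where overlapping ones were joined and covered 1.30% of the chromosome arms. Regions had a median width of 404 bp. The authors' signal per site ran from 134 to 7767, with a median of 259. The read depth behind these values is unknown.

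Most of the strongest sites lay within 500 bp of a TSS, at genes of varied function. The strongest of all (signal 7767) was on chromosome 3L from 19590388 to 19590851 (dm6), with its summit 95 bp from the TSS of CG14100. The next was in an intron of ph-p, which encodes a subunit of a Polycomb repressive complex, 475 bp from a TSS on X from 2137112 to 2137602 (signal 7267). It was followed by px, a gene of wing vein patterning, on 2R from 22514060 to 22514525 (signal 7034), and Art3, which encodes an arginine methyltransferase, on 3R from 15229305 to 15229775 (signal 6861).

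Of the 20 strongest sites, 13 were promoter sites, and all 20 ranked 39 or higher in replicate 1 and 24 or higher in replicate 3. The promoter sites also included CG13921, CG1888, the mitochondrial ribosomal protein gene mRpL41, Pal1, Tcs5, Ugalt, CG5611, Fkbp14 and CG18428. Introns held the sites in Lrch (signal 4865), in the kinase genes Tlk (signal 4184) and Lk6 (signal 3690), and the site nearest to cbt, which lies inside ush (signal 4772). The sites nearest to CycB, the mitotic cyclin B gene, and to DNAlig3 were intergenic, and the site nearest to hll lay in a non-coding gene. The 41 bases centred on the CG14100 summit, on 3L from 19590599 to 19590639, read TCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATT. The window reaching 50 bp to either side of this summit had a GC content of 30.7%.

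The tagged gene's own locus held 1 site. CG15696 lies on 3R from 20847068 to 20847748 on the plus strand. The site was on 3R from 20850379 to 20850782, with its summit 2833 bp past the end of the gene, and ranked 2996 of 5354 (signal 234). The matching peak ranked 1484 in replicate 1 and 5567 in replicate 3. Over all protein-coding genes, the median number of sites within 10 kb was also 1 and the 95th percentile was 4.

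The replicates shared nearly all strong sites, and shared most weak ones when their full lists were used. Of the 5354 sites, 3892 (72.7%, 95% interval 71.5 to 73.9%) had a summit within 100 bp among the equally long lists of strongest peaks of both replicates. Replicate 1 held 81.9% and replicate 3 held 89.4% of sites by this rule. Over 4 strata of equal size, from the highest signal to the lowest, the share in both was 98.6%, 94.1%, 72.9% and 25.2%. The weakest sites lie at the rank where these lists end, which lowers their share by construction. Within the full lists of 30000 peaks, 94.3% of sites had a partner in both replicates, and over the same strata 98.9%, 97.2%, 93.6% and 87.5%. The IDR list, which its label calls optimal, was derived with a measure of rank agreement. Which comparison of peaks set its threshold is not given, so high agreement between these replicates may follow in part from its construction. Its members are nevertheless the pooled peaks of highest signal, and 10 of them had no partner in either full list. Across the 5049 sites matched in both full lists, signal in the 2 replicates had a Spearman correlation of 0.721 ± 0.00836 (bootstrap SE over sites) and a Pearson correlation of 0.789 on the log2 scale.

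Promoters took the largest share of sites, and coding exons almost none. Of 5354 summits, 2245 (41.9%, 95% interval 40.6 to 43.3%) lay within 500 bp of a protein-coding TSS, against 11.5% ± 0.438 (SD over random sets) of random positions, a 3.66-fold excess (permutation p = 0.0002, the smallest that 10000 sets can give). Introns held 34.0% of summits and intergenic sequence 19.9%, against 39.3% and 28.0% of the genome. Coding exons outside promoters held 9 summits (0.168%, 95% interval 0.0885 to 0.319%) against 13.9% of the genome, and 3' UTRs held 0.971% against 4.51%. The median distance to the nearest TSS was 954.5 bp. Against random positions with the same GC content, a control chosen after seeing the data, promoters were still 3.59-fold over-represented, and coding exons held 0.168% of summits against 3.94% (exact sign test, p = 5.25e-48).

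**Figure D1:**
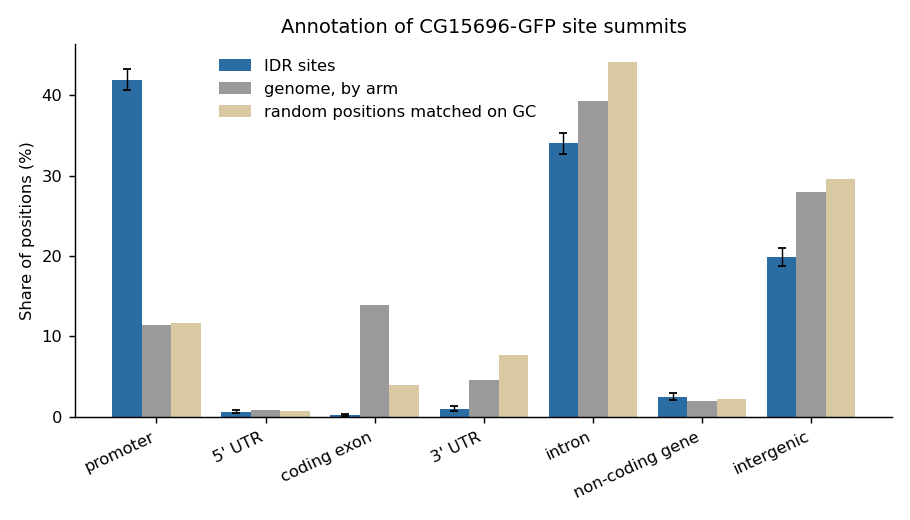
Share of positions (%) in each annotation class for the 5354 IDR site summits (blue, with 95% Wilson intervals), the genome weighted by arm (grey) and random positions matched on GC content (tan). Promoters held 41.9% of summits against 11.5% of the genome, and coding exons 0.168% against 13.9%.

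Stronger sites were more often at promoters in the combined list, and the replicates differed on this. The promoter share was 44.6% among the 1338 strongest sites and 39.7% among the 1338 weakest, a difference of 4.93 percentage points (Fisher's exact test, two-sided, p = 0.0109). With replicate 3 alone the difference was 10.01 points (Fisher's p = 2.07e-07), and with replicate 1 alone it was -4.41 points (p = 0.0228), so its direction depended on the replicate. It also lost significance with promoter windows of 200 bp (1.87 points, Fisher's p = 0.312) and 1000 bp (2.84 points, p = 0.152).

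Sites at promoters had relatively more signal in replicate 3, and sites in introns relatively more in replicate 1, a comparison chosen after seeing the data. The 5049 matched sites were divided into 4 strata of equal size by the ratio of signal in replicate 3 to signal in replicate 1. Promoters made up 64.1% (95% interval 61.4 to 66.7%) of the stratum towards replicate 3 and 27.9% (25.5 to 30.4%) of the stratum towards replicate 1. The difference was 36.2 percentage points (Fisher's exact test, two-sided, p = 4.33e-76). Introns made up 18.9% and 46.4% of the same strata. The sequence CAAACA lay within 50 bp of 28.3% of summits in the stratum towards replicate 1 and of 9.19% in the stratum towards replicate 3, and TTAAAA of 19.0% and 39.1%. Ribosomal protein genes went against the promoter trend, with a mean log2 ratio of 0.09 against 0.80 for all genes with a site (permutation test, adjusted p = 0.0013). These tests compare 2 libraries of 1 group, not conditions.

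**Figure D2:**
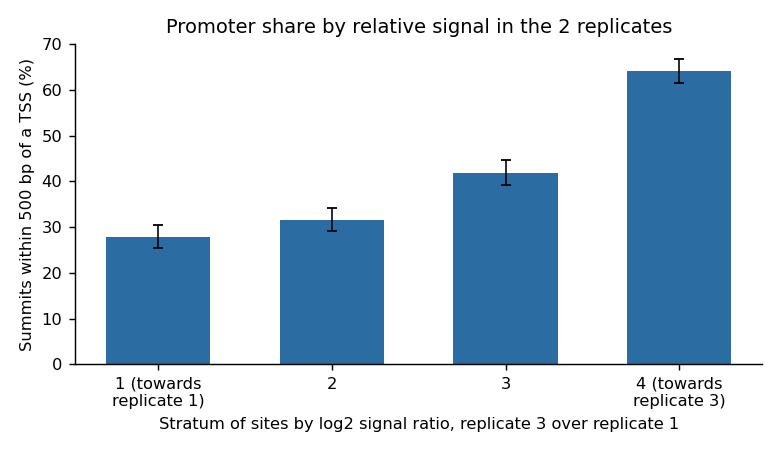
Share (%) of summits within 500 bp of a protein-coding TSS in 4 strata of the 5049 sites matched in both replicates, ordered by the log2 ratio of authors' signal in replicate 3 to replicate 1 (bars, with 95% Wilson intervals). The share was 27.9% in the stratum towards replicate 1 and 64.1% in the stratum towards replicate 3.

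The X chromosome had a site density close to that of the autosomes. There were 38.3 sites per Mb on X and 40.6 on the major autosomal arms, a ratio of 0.943 that did not pass the test (exact binomial test, two-sided, p = 0.114). Arm 2L had 43.8 sites per Mb and 2R had 35.6. Chromosome 4, which is largely heterochromatic, had 36 sites, or 27 per Mb. With replicate 1 alone the ratio of X to autosomes was 0.895 (exact binomial p = 0.00274), and among the stronger 2677 sites it was 0.871 (p = 0.00903).

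Ribosomal protein genes and Notch and EGFR targets had sites more often than matched random genes, and chemoreceptor genes less often. Of 85 ribosomal protein genes, 62 (72.9%) had a site in the body or within 2 kb, against 25 expected, a ratio of 2.48 (permutation test, adjusted p = 0.00019). Of 15 Notch and EGFR targets, 12 had a site against 5.49 expected, a ratio of 2.19 (permutation test, adjusted p = 0.0038). That name stands for the whole list, which joins E(spl) genes and aos with genes of the pathways themselves (N, Dl, spi, pnt and Egfr). Of 179 chemoreceptor genes, which encode odorant, gustatory and ionotropic receptors, 15 (8.38%) had a site against 61.2 expected, a ratio of 0.245 (permutation test, adjusted p = 0.00019). Among all 13945 protein-coding genes, 5192 (37.2%) had one.

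Strong sites in ribosomal protein gene territories included those of RpL3 (rank 244), RpL34b (rank 340) and RpL13A (rank 436). The first of these is nearest to the TSS of CG17726 and the last to that of Dph4, both neighbouring genes. With a site required within 500 bp of a gene's own TSS, an assignment chosen after seeing the data, 52 of the 85 ribosomal protein genes had one against 14.6 expected. By the same rule 1 of the 179 chemoreceptor genes had one against 37.6 expected. The strongest site assigned to a chemoreceptor gene, Or85f, is the site nearest to the TSS of RpL34b. The other chemoreceptor genes named by the rule were Gr97a (rank 765), Gr89a (rank 766) and Or88a (rank 1343).

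The excess among Notch and EGFR targets came mainly from the E(spl) complex, a cluster of adjacent genes on 3R for Notch-induced transcriptional repressors and related proteins. In a split of the list made after seeing the data, 7 of 9 E(spl) genes had a site against 2.01 expected (permutation p = 0.0015). Of the 6 other genes, 5 (Egfr, N, aos, pnt and spi) had one against 3.48 expected (permutation p = 0.406), which left little room for an excess. With a site required at the own TSS the counts were 5 of 9 against 0.969 expected and 4 of 6 against 1.72. The 2 parts were not tested against each other. E(spl)m7-HLH had the strongest site of the list, on 3R from 26036426 to 26036890 (rank 58, signal 2407). The next were those of E(spl)mdelta-HLH (rank 67, a site whose nearest TSS is that of CG43116, 268 bp away), E(spl)m3-HLH (rank 203) and aos (rank 272), which encodes an EGFR inhibitor. Adjacent genes can share sites and are not independent, which the random gene sets do not take into account.

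No list of patterning or tissue genes differed from matched random genes in the planned test, although several held very strong sites. The test left little room for an excess where the expected share was high, as for Hox genes (4.82 of 8 expected). The lists of segment polarity genes (8 of 13 with a site), Hox genes (6 of 8), dorsal ectoderm and amnioserosa genes (9 of 15), neuroectoderm column genes (7 of 10), mesoderm and muscle genes (13 of 19), endoderm and gut genes (7 of 9) and trachea and epidermis genes (7 of 9) had adjusted p values from 0.663 to 0.813. Pair rule genes (4 of 9) and the NKL homeobox class to which CG15696 belongs (8 of 20) did not pass the test either. Gap and head gap genes had 3 of 11, neuroblast and proneural genes 6 of 16, differentiated neuron genes 4 of 10, glial genes 6 of 10, cellularisation genes 3 of 6 and germ line genes 4 of 11. Only Hml of the 10 haemocyte genes had a site, against 4.76 genes expected (permutation test, adjusted p = 0.131), and without replicate 3 none had (adjusted p = 0.0169). With sites assigned to the nearest TSS alone, 8 lists lay above their random sets in place of 2. The random genes were still matched on territory length, and not on the distance to neighbouring TSSs, on which this assignment depends. The added lists were pair rule (7 of 9), segment polarity (11 of 13), Hox (8 of 8), dorsal ectoderm and amnioserosa (10 of 15), neuroectoderm columns (8 of 10) and endoderm and gut (8 of 9). The Hox list and the endoderm and gut list share lab and Abd-B. With a site required within 500 bp of the own TSS, chosen after seeing the data, none of these lists passed. Only endoderm and gut genes (3 of 9, against 2.60 expected) then lay above expectation.

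Among these genes the strongest sites lay in territories of genes of several tissues, some of them nearer to the TSS of another gene. The best rank in a territory was not compared with that of matched random genes. Mef2, the muscle differentiation factor, held the site of rank 13, which is also the site at the TSS of Pal1 inside its territory, with zfh1 (rank 108), kirre (rank 122) and Poxm (rank 315) next among mesoderm and muscle genes. In the ectodermal lists ush, a GATA factor partner, held 10 sites including rank 7, followed by slp1 (rank 32), the neuronal gene elav (rank 55), grh (rank 61), sim (rank 137), Doc2 (rank 148) and nkd (rank 151). The gut regulator bowl held the site of rank 103. The Hox gene Antp held 9 sites, the strongest of rank 189, and lab held 5, the strongest of rank 365. The NKL gene tin, a regulator of heart and dorsal mesoderm, had 1 site, of rank 328.

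**Figure D3:**
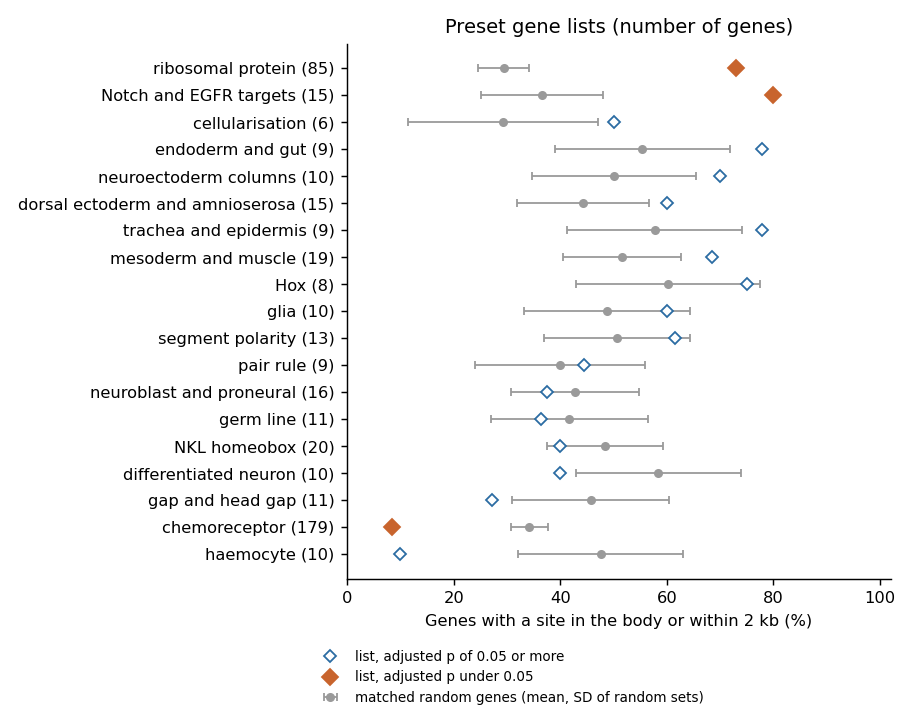
Share (%) of the genes in each of 19 preset lists with an IDR site in the gene body or within 2 kb (diamonds, filled where the adjusted p was under 0.05), beside the mean and SD of random gene sets of the same size and territory length (grey). Ribosomal protein genes (72.9%) and Notch and EGFR targets (80%) lay above their random sets, and chemoreceptor genes (8.38%) below.

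The homeodomain motif TAATTA was more frequent at summits than in their flanks, but not more frequent than at other positions of the same base composition. TAATTA lay within 50 bp of 10.6% of summits (95% interval 9.83 to 11.5%) and in 5.58% of flanks, a ratio of 1.90 (exact sign test, adjusted p = 1.97e-21). TAATGA (ratio 1.42) and TAATTG (ratio 1.23) were also more frequent, and TAATGG (1.08) and TAATCC (1.05) did not pass the test. Against random positions with the same GC content the ratio for TAATTA was 0.918 (exact sign test, adjusted p = 0.138). TAATTG (0.849), TAATGA (0.832) and TAATGG (0.83) were less frequent at summits (exact sign test, adjusted p = 0.0478, 0.00807 and 0.0168). TAATCC had a ratio of 0.744 (exact sign test, adjusted p = 0.0532). Summits were AT-rich, with a mean GC content of 32.5% within 50 bp against 43.8% at 350 bp.

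Other preset motifs behaved differently under the 2 controls. The TATA box was found at 24.3% of summits and 10.5% of flanks (ratio 2.33, exact sign test, adjusted p = 7.14e-82), but its ratio to GC-matched positions was 1.04 (adjusted p = 0.567). The DREF motif, found at promoters of housekeeping genes, was at 1.16% of summits with a ratio of 3.10 against both controls. Its ratio to flanks was 1.88 among the stronger 2677 sites (exact sign test, adjusted p = 0.178) and 5.29 with replicate 1 alone. Within 200 bp of summits DREF was at 6.16% of sites, a ratio of 5.45 to flanks 500 bp away (exact sign test, adjusted p = 3.33e-47). CATATG, an E-box bound by factors such as twist, had ratios of 1.68 and 1.58, and the GATA factor motif 1.59 and 1.12, all past an adjusted p of 0.05. The motif of motif 1 binding protein had ratios of 1.38 (exact sign test, adjusted p = 0.297) and 3.05 (adjusted p = 0.00208). To flanks, the ratio was 2.91 with replicate 1 alone (exact sign test, adjusted p = 0.00106). With replicate 3 alone it was 1.08 and among the stronger 2677 sites 0.625, neither past the test. The GAGA factor motif (ratio to flanks 0.624) and the E-box CAGCTG (0.548) were less frequent at summits than in flanks, and their ratios to GC-matched positions were 1.22 and 1.11, neither past the test. The Zelda motif passed neither test (0.662, exact sign test, adjusted p = 0.0629, and 0.917, adjusted p = 0.725). In its test against flanks, 99 sites had the motif only at the summit and 130 only in the picked flank. In all, 7 of 20 preset motifs were more frequent and 7 less frequent at summits than in flanks.

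Among all 2080 6-mers, 498 were more frequent at summits than in flanks and 1103 less frequent. The 5 with the highest ratios were ATATTA (22.4% of summits, ratio 3.17), AATATT (21.3%, 2.99), TATTAA (21.9%, 2.89), AATATA (26.4%, 2.81) and TTTAAA (21.9%, 2.77), all made of A and T. TAATTA ranked 115 of 2080 by ratio. Against GC-matched positions 142 6-mers were more frequent, and the 5 with the highest ratios among those in at least 5% of sites, chosen after seeing the data, were ACAGTG (5.23% of summits, ratio 1.84), CAGTGC (5.32%, 1.78), ACACTG (5.10%, 1.74), GTAAAC (8.65%, 1.71) and CACTGA (5.19%, 1.62).

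Of the 20 preset motifs, 7 differed in frequency between strong and weak sites, 2 of them being more frequent at strong sites and 5 at weak ones. Between the 1338 sites of highest and the 1338 of lowest signal, TAATTA was at 13.3% and 8.59% of summits (Fisher's exact test, two-sided, adjusted p = 0.00118) and the TATA box at 28.5% and 20.1% (adjusted p = 1.07e-05). DREF was at 0.448% and 1.87% (Fisher's exact test, adjusted p = 0.00411) and the motif of motif 1 binding protein at 0.0747% and 1.12% (adjusted p = 0.00334). The GAGA factor motif (1.64% and 3.51%), CAGCTG (1.87% and 3.81%) and the CA repeat (5.98% and 8.74%) were also more frequent at weak sites. TAATTG (11.1% and 10.3%) and TAATGA (8.37% and 8.30%) did not pass the test. Stronger summits were also lower in GC content, with 29.4% for ranks 1 to 1000 and 33.2% for ranks 1001 to 5354. In position profiles made after seeing the data, 7 of 20 motifs were denser within 50 bp of the summit than at 100 to 150 bp, and 11 were denser at 100 to 150 bp. The GAGA factor motif had 0.415 matches per kb within 50 bp of summits, 0.990 at 100 to 150 bp and 0.616 at 400 to 700 bp (exact binomial test of the first against the second, adjusted p = 6.65e-29). These tests counted matches and not sites, and several matches in 1 site are not independent, which makes such p values too small. CAGCTG had 0.288, 0.704 and 0.520. DREF (0.131, 0.215 and 0.0255) and the motif of motif 1 binding protein (0.0579, 0.192 and 0.0274) were also denser beside the summit than at it. TAATTA had 1.23, 0.667 and 0.658. Summit positions are those of the authors' peak caller, and any offset of them from the bound sequence was not tested, which limits every value given at summits.

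**Figure D4:**
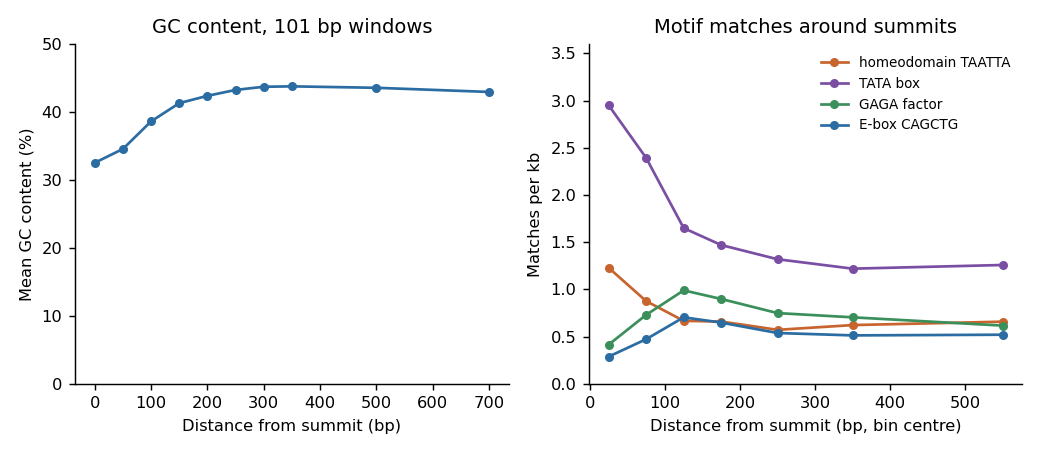
Left, mean GC content (%) of windows reaching 50 bp to either side, by distance from the 5354 summits (bp, both sides averaged). Right, matches per kb of 4 motifs by distance from the summit (bp, bin centres), where TAATTA and the TATA box were densest within 50 bp and the GAGA factor motif and CAGCTG at 100 to 150 bp.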

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

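The tests of base composition, for which a control fixed in advance was used, of a gene's own TSS and of the replicate balance were chosen after the results were seen; the comparison with ribosomal protein genes, and that of the Zelda and GAGA factor motifs, were fixed before the data were examined.

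Peaks just below the reproducible set recurred in both replicates, which drew attention as a signal in data that the comparisons do not use. Of the 5354 pooled peaks ranked 5355 to 10708, 73.1% had a summit within 100 bp in both full replicate lists, against 0.198% on average and 0.374% at most with shifted summits. Pooled peaks were called on the reads of both replicates, so an overlap above that of shifted summits follows in part from the construction.

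The TATA box and 3 of the 5 homeodomain motifs were more frequent at summits than in flanks. Base composition is a candidate explanation for these: TAATTA had a ratio of 1.90 to flanks and 0.918 to GC-matched positions, and the GC content rose from 32.5% at summits to 43.8% at 350 bp. Base composition is argued against for CATATG and DREF, whose lower ratio to GC-matched positions was 1.58. Of those positions 11.7% were promoters, against 41.9% of summits, and this difference was not separated from the ratios. DREF was at 2.49% of promoter sites (ratio to flanks 3.61) and at 0.193% of other sites (ratio 1.33). CATATG was at 3.79% (ratio 1.47) and 6.05% (ratio 1.80). Whether summits carry the sequence of accessible embryonic chromatin stays open, because the planned comparison set the TAAT motifs (highest ratio 1.90) above Zelda and GAGA factor (highest 0.662) in flanks of another base composition, and the order turned to 0.918 and 1.22 with GC matched. No biological explanation was tested, since the design holds no embryos without the tagged protein.

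Sites lay near genes of the Notch and EGFR list more often than chance, and near chemoreceptor genes less often (8.38% of them). General ChIP signal at highly transcribed genes may account for part of this, since ribosomal protein genes, which are not a developmental list, had a ratio of 2.48 (permutation test, adjusted p = 0.00019). Sites that belong to neighbouring genes are argued against as the cause. Notch and EGFR targets with a site at their own TSS had a ratio of 3.35 (permutation test, adjusted p = 0.00266). With each site given to its nearest TSS alone the ratio was 2.57 (permutation test, adjusted p = 0.00342), against random genes matched on territory length only. However, a neighbour's TSS can lie within 500 bp of the same site. Transcription was not measured here, and binding of CG15696 to promoters of active genes would give the same counts. No biological explanation was tested.

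Promoter sites had relatively more signal in replicate 3. The difference in promoter share between the outer strata, 36.2 percentage points, was 33.3 points (95% bootstrap interval 29.5 to 37.1) within 5 strata of GC content and 36.0 points (32.1 to 39.6) within 5 strata of pooled signal, so neither the GC content of the sites nor their overall strength accounts for more than a small part of it. What stays open includes a difference in depth, enrichment or fragment size between the libraries and a different mix of embryo ages within the 2 to 8 h window, none of which the files resolve. No biological explanation was tested.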

How the results depend on the processing

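Of 51 alternative values of the planned comparisons, 34 were counted as unchanged. They include the promoter share under each alternative (29.9 to 50.5%) and the pooled list, which moves nothing by construction. Tested shares, differences and ratios were counted as unchanged if they kept their direction and their side of the threshold. Counts of regions, lists, motifs or 6-mers needed only to stay close in size to the main count, whatever their members. The count of preset motifs more frequent at summits is among the 34 with GC-matched positions (5 against 7), but its members changed. GC-matched positions for the promoter share and assignment by own TSS were chosen after seeing the data. A stricter threshold left 2677 sites, by construction. Replicate overlap was 61.8% with summits within 50 bp, 77.4% within 250 bp, 77.5% with regions sharing 1 bp, 58.8% with regions sharing 50% of each and 94.3% with full replicate lists, as wider rules admit more. The signal correlation was 0.754 with summits within 50 bp, 0.702 within 250 bp and 0.690 among the stronger sites. The strength difference in promoter share ranged from -4.41 points without replicate 3 to 10.01 without replicate 1, and was 3.59 with the stricter threshold, 1.87 with a 200 bp window and 2.84 with a 1000 bp window. The ratio of X to autosomes ranged from 0.895 without replicate 3 to 0.984 without replicate 1, and was 0.871 with the stricter threshold. Assignment to the nearest TSS gave 8 lists above random sets that were not matched for that assignment, against 2. GC-matched positions gave 142 6-mers against 498. Of the 311 values for single lists and motifs, 14 changed direction where the main or the alternative value passed its test, and changes of direction where neither passed are not counted. With GC-matched positions these were the ratios of TAATTA (0.918), TAATTG (0.849), TAATGA (0.832), TAATGG (0.83), the NK-2 type (1.01), GAGA factor (1.22), CAGCTG (1.11), CAGGTG (1.24), the CA repeat (1.22), the odd-paired type (1.38) and Suppressor of Hairless (1.10). With windows of 200 bp and flanks at 500 bp, changed together, they were TAATCC (0.817), GAGA factor (1.20) and CAGCTG (1.02). Another 13 came to pass the threshold and 9 no longer did. The former include the haemocyte list without replicate 3 (0 of 10 genes), the Zelda motif without replicate 3 (0.721) and the motif of motif 1 binding protein in 4 settings (1.94 to 4). The latter include Suppressor of Hairless in 4 settings (0.641 to 0.964), DREF with the stricter threshold (1.88) and the TATA box with GC-matched positions (1.04). Apart from the base composition of flanks and the rules named, the cause was not tested. The read depth is unknown and its effect was not tested. Of the weakest sites in the reproducible set, 87.5% were in both full replicate lists.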

Other observations

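The count of reproducible sites at the tagged gene's own locus was fixed before the data were examined; the other values here, with the count of pooled peaks there, were chosen after seeing the data.

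The genes with most sites in the body or within 2 kb had long territories. CG1677 held 19 sites in 129 kb, kirre 18 in 398 kb, hth 15 in 136 kb, px 13 in 71.8 kb and rdx 13 in 69 kb. No test took territory length into account for these counts. Of the 87 different sites in ribosomal protein gene territories, 79 were promoter sites, and of the 18 in chemoreceptor gene territories, 9 were.

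Base composition and gene structure changed along the pooled list. The mean GC content at summits was 29.4% for ranks 1 to 1000, 33.2% for ranks 1001 to 5354, 37.2% for ranks 5355 to 10708 and 41.7% for ranks 20001 to 30000. Over the same ranges the promoter share was 45.6%, 41.1%, 36.3% and 16.8%, and the share in coding exons was 0.2%, 0.161%, 0.915% and 10.1%.

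Single sequences differed in frequency between the strata of sites towards replicate 1 and towards replicate 3, which also differ in GC content (36.7% and 31.7%) and promoter share, and neither was controlled for here. CA repeats lay within 50 bp of 13.8% of summits in the former and 4.60% in the latter (Fisher's exact test, adjusted p = 1.27e-14), GTAAAC at 15.3% and 5.23%, and TAATTA at 6.97% and 12.5% (adjusted p = 2.39e-05). Of 2080 6-mers, 154 were more frequent towards replicate 1 and 147 towards replicate 3. Chemoreceptor genes with a site had a mean log2 ratio of replicate 3 to replicate 1 of -0.01, against 0.80 for all genes with a site (permutation test, adjusted p = 0.0013).

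The locus of CG15696 held 1 site within 10 kb, the median of all genes being 1. The pooled list held 9 peaks within 5 kb of the gene against a median of 4, a count reached by 12.5% of genes. Their −log10 q values ran from 3.97 down to 0.137, so not all of these peaks are well supported. Whether extra copies of the locus carried by the transgene raised the signal there stays open.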
